A study of Mus musculus with 5 samples.

How the data were processed

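Gene expression was measured on 1-colour Affymetrix whole-transcript arrays in erythroid cells of mouse bone marrow. There were 5 arrays, 2 from wild-type (WT) mice and 3 from mice homozygous for a mutant allele of Polg, the gene of the mitochondrial DNA polymerase. Per the labels' protocols, marrow cells bearing CD45, the common leukocyte antigen, were depleted on a magnetic separator, and cells bearing the erythroid antigen Ter119 were then selected from the rest. Column-purified total RNA, 100 ng per sample, was copied into sense-strand cDNA, fragmented and labelled with biotin, per the labels' protocols. The series' design text states that the mice had been phlebotomized, while the treatment field of each label reads none. The schedule of bleeding and the ages of the mice were not given in the sources used here. All samples carry the same breeding label, in which both parents had floxed Atg7 alleles and the father carried 1 Epo-cre allele. Which offspring inherited the Cre allele was not given in the sources used here.

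The authors deposited 1 table of log2 expression values for 41345 probe sets, with 1 column per array and no pooling. RMA and Partek 6.5 were the tools named, per the submitters' processing notes, with no role or order. The probe annotation and genome build behind the values were not given in the sources used here. The log2 scale was read from the values, which ran from 1.43 to 14.1, with array medians between 5.10 and 5.13. The deposited log2 values were used as they stood, with no further background correction or scaling. Scanner files were not used here, so signal over background was not known for any probe set. The number of arrays alone limits the precision of each value.

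Probe sets were named through the platform's annotation table. That table gave 1 gene symbol for 23521 probe sets, several for 1814 and none for 16010. Only probe sets with 1 symbol were named, and for the 1082 genes with more than 1 such probe set the brightest over all arrays was kept, which left 22180 genes. No probe set was removed for being dim. Bnip3l, Alas2, Gdf15, Ddx3y and the adult globin genes had no probe set paired with their symbol alone and were not analysed here.

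The WT and Polg mutant groups were compared with limma 3.58.1 in R 4.3.3, by a linear model with genotype as its single term over all 5 arrays and empirical Bayes moderation of the variance without a trend. Tests were two-sided, p-values were adjusted over all genes tested by the method of Benjamini and Hochberg, and the threshold was an adjusted p under 0.05. Differences are given as log2 Polg mutant minus WT with the standard error (SE) of limma's moderated test, and group levels as mean ± SD with 2 WT and 3 Polg mutant arrays. The labels do not state that the arrays came from separate animals, so the p-values measure only the spread between these samples, which may be technical. An exact permutation test of single genes could not go below p = 0.1, because 5 arrays give 10 splits into groups of 2 and 3.

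Gene lists covering mitochondria, stress responses, autophagy, erythroid differentiation, metabolism, proteostasis, the cell cycle, immune responses, other marrow cell types and sample checks, 45 in all, were fixed before the data were examined, as were the design, the named genes' rule and all alternatives not described as added. Of 1064 symbols fixed by name, 959 were measured, and 44 lists with at least 5 measured members were tested. Each list was set against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists tested. Camera with an estimated correlation and fry, which asks whether a list's own genes move one way, were run beside it. Fry's mixed test asks whether those genes differ in either direction. Members were also counted with p-values adjusted over the list alone. The text names 12 genes in each direction, those of largest difference among non-overlapping genes past the threshold. Where too few passed, non-overlapping genes of smallest p with a difference of at least 0.5 filled the places. Genes with only a RIKEN, Gm, LOC or other provisional symbol were left out of these 12, as were Olfr, Vmn, Mir and Snor symbols. The text also names up to 4 members of each list by smallest p, and a fixed set that includes Polg, Atg7, Atf4 and Cdkn1a. Any gene named outside this rule is said to have been chosen after its values were seen.

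The deposited values hold exact ties between arrays. Of all probe sets, 56.6% had the same value on at least 2 of the 5 arrays, and 1553 had a single value on all 5. Among the genes tested, 15068 (67.9%) were tied in this way. The ties lowered limma's estimate of the typical variance and of its reliability: the prior SD was 0.0376 with 0.730 prior degrees of freedom over all genes, against 0.170 with 3.17 over genes with 5 distinct values. Alternatives added after this was seen were the fit to untied genes, the fit to untied genes above a log2 of 6 on at least 2 arrays, and a prior variance taken from untied genes.

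The fit was tested on simulated data with the same design, in which probe-level values were summarised by median polish and 200 of 22180 genes were changed. In the simulated comparison of Polg mutant with WT over 22180 genes, limma recovered 33% of genes changed by 1 log2 unit and 80% of those changed by 2, with 1 false call. Over the 7660 simulated genes with 5 distinct values it recovered 87% and 100%, with 6 false calls. The array-to-array variation was drawn smaller than the observed SD of untied genes, and genes varied independently. These recovery rates may therefore be too high for the real data. There, 20 genes higher and 5 lower by at least 2 log2 units, without overlap, all missed the threshold over all genes. Median polish of 5 simulated arrays left 65.5% of probe sets tied, and of 4 arrays 0.0135%.

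Other alternatives were the replicate number as a block, each array left out in turn, renewed quantile normalization, centring on the median or on the brighter part of the genes, filters on dim genes, a trended or robust prior, array weights, no moderation, the mean over probe sets, all probe sets, and other thresholds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.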

Results

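Gene expression was compared between erythroid marrow cells of WT mice and of Polg mutant mice, also known as mtDNA-mutator mice, whose mitochondrial DNA polymerase lacks proofreading and which accumulate mutations in mitochondrial DNA. Ter119, the antigen used for selection, marks erythroid cells from the erythroblast stage to the red cell. There were 2 WT and 3 Polg mutant arrays, each with 41345 probe sets, and array medians lay between 5.10 and 5.13 on the log2 scale. Across genes, Pearson's r was 0.990 between the WT arrays, 0.990 to 0.995 between Polg mutant arrays and 0.983 to 0.991 between groups, over genes that are not independent replicates. The first principal component of the 2000 most variable genes held 51.6% of their variance and put both WT arrays on one side (-0.48 and -0.58) and all Polg mutant arrays on the other (0.19 to 0.57). The second component held 27.2% and did not follow genotype, since it set WT replicate 2 and Polg mutant replicate 3 (0.43 and 0.59) apart from the other arrays (-0.62 to -0.18). Mean levels of the neutrophil marker list divided the arrays in the same way, at 6.70 and 6.85 against 7.50 to 8.31. Whether granulocyte content gave rise to this component was not tested.

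The series asked which genes and pathways differ between Ter119-selected marrow cells of phlebotomized WT and Polg mutant mice. In the Polg mutant cells, targets of the stress transcription factor ATF4 and genes of cytosolic ribosomes rose as groups, while genes of mitosis, DNA replication and the red cell membrane fell as groups, by camera at a preset correlation. With an estimated correlation none of these 5 lists passed (adjusted p from 0.231 to 0.417). Fry passed the ATF4, ribosomal protein and mitosis lists (fry adjusted p = 0.0410 each). It did not pass DNA replication (fry adjusted p = 0.132) or the red cell membrane (0.0505). The cystine transporter gene Slc7a11 was 14.7-fold higher, with a log2 difference of 3.87 ± 0.16 (SE; 2 WT and 3 Polg mutant arrays), and Cth, which makes cysteine from cystathionine, was 13.1-fold higher. Their WT levels, 4.16 and 4.02, lay near the lower quartile of the arrays (3.95 to 4.02) and were not shown to be above background, so these folds are not exact and may be too low. Cdkn1a, which encodes the cell cycle inhibitor p21, was 7.93-fold higher, and Erfe, the erythroid hormone that lowers hepcidin, 4.87-fold higher. Camera, which looks for a shift in a single direction, did not call the autophagy and mitophagy lists.

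Single genes were tested first. With limma, 0 genes were higher and 0 lower past the threshold over all 22180 genes tested, and the smallest adjusted p was 0.0851. At an unadjusted p under 0.05 there were 927 higher and 1183 lower genes, 2110 in all, where chance would give 1109. The balance of directions depended on the scaling, with 1129 higher and 1116 lower after renewed quantile normalization, 924 and 1293 after median centring and 838 and 1490 after centring on the brighter part of the genes. Without moderation of the variance, 4 genes passed as higher and 1 as lower. Restricting the fit to genes above a log2 of 6 on at least 2 arrays gave 6 higher and 5 lower genes. Restricting it further to the 4322 of these without ties, a choice made after the data were seen, gave 247 higher and 240 lower. That further filter is not independent of the differences tested. In the simulation at least 87% of genes changed by 1 log2 unit and 100% of those changed by 2 were untied, against 7660 of all 22180 genes. Without WT replicate 1 the count of genes higher in Polg mutant past the threshold was 713 and of genes lower in Polg mutant past the threshold 1068, and without WT replicate 2 these were 511 and 413, in fits where the lone WT array is assumed to vary as the Polg mutant arrays do. The groups did not overlap for 1854 higher and 2158 lower genes, 18.1% of those tested, where chance gives 20% when no values are tied.

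**Figure D1:**
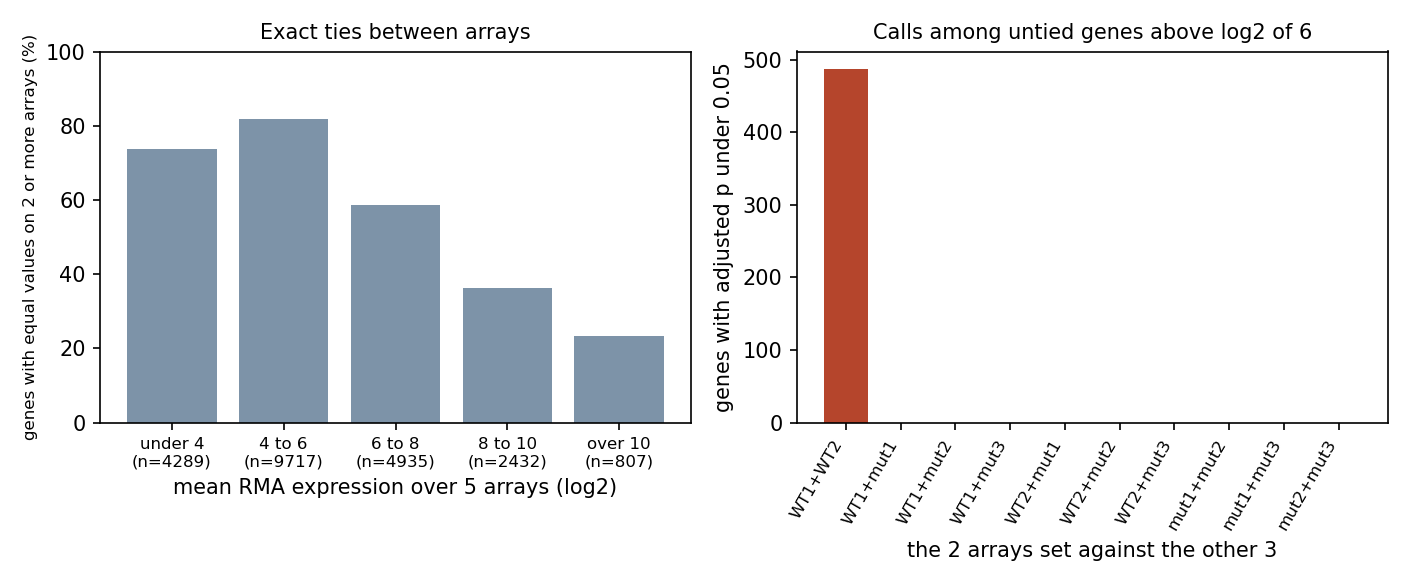
Left, percent of genes in each class of mean log2 expression whose values were exactly equal on at least 2 of the 5 arrays, from 81.7% between 4 and 6 to 23.4% over 10. Right, number of untied genes above a log2 of 6, a set chosen after the data were seen, with a limma adjusted p under 0.05 for each choice of 2 arrays set against the other 3, with 487 for the real WT pair (red) and 0 for each other pair.

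The genes of smallest p that were higher in the Polg mutant included Trim12c, a tripartite-motif gene, by 1.39 ± 0.04 (SE, limma adjusted p = 0.0851). Slc7a11 went from 4.16 ± 0.31 (SD, n = 2) in WT to 8.03 ± 0.10 (SD, n = 3) in the Polg mutant on the log2 scale, with a limma adjusted p of 0.103. Tmem67, a ciliary transition-zone gene, and its neighbour Rbm12b2 were 12.8-fold and 5.80-fold higher, from WT levels of 5.49 and 5.48 that were not shown to be above background either. Nupr1, a stress-induced nuclear protein gene, was higher by 1.28, the carboxypeptidase gene Cpd by 1.40 and the RNA-editing deaminase gene Apobec1 by 1.17. The mitochondrial chaperone genes Hspd1 and Hspa9 were higher by 0.65 and 1.11, the ribosomal protein genes Rpl13 and Rpl29 by 1.14 and 0.67, and Gng5, a G-protein subunit gene, by 1.21. Among genes that were lower, Parp16, an endoplasmic reticulum ADP-ribosyltransferase gene, differed by -1.05 ± 0.04 (SE) and Tmem65, an inner mitochondrial membrane protein gene, by -0.91 ± 0.03, each with a limma adjusted p of 0.0851. Liph differed by -0.90, between levels of 5.17 in WT and 4.26 in the Polg mutant that were not shown to be above background. Akap7 differed by -0.99, Tmc6 and Dnajb3 by -0.84 each, Ermp1 and the erythroid long noncoding RNA gene Redrum by -0.74 each, and the mitotic kinase gene Ttk by -0.65. Brf1, a subunit of the RNA polymerase III initiation factor, differed by -0.64, Arrdc3 by -0.60 and Cecr2 by -0.58. In the planned fit to genes above a log2 of 6, Slc7a11, Rbm12b2, Cpd, Trim12c, Nupr1 and Apobec1 passed as higher, and Parp16, Tmem65, Dnajb3, Tmc6 and Brf1 as lower, with limma adjusted p from 0.0405 to 0.0498.

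Of the 44 gene lists tested with camera, 13 rose and 7 fell in the Polg mutant. With an estimated correlation 0 lists passed, with adjusted p from 0.231 to 0.813 for the 20 lists called at the preset correlation, and fry passed 7 of them and had 15 at an unadjusted p under 0.05. Camera called 18 lists without WT replicate 1 and 16 without WT replicate 2, and 12 of the 20 lists were called in each of the 5 fits that left out an array. Setting Polg mutant replicates 1 and 2 against the other 3 arrays also gave 20 lists, so the count of lists does not set genotype apart from other differences between these arrays.

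The ATF4 list holds the genes of the integrated stress response, in which ATF4 turns on amino acid synthesis, transport and redox genes. It rose by a median of 0.45 log2 units over 38 measured genes (camera adjusted p = 2.00e-13, and adjusted p = 0.311 with an estimated correlation). In 22 of these genes every Polg mutant array lay above both WT arrays, and in 1 below both, where chance gives 20% of untied genes in either direction together. With limma, 17 members had an unadjusted p under 0.05, 14 were higher past the threshold when adjusted over the list alone, and 0 over all genes tested. Slc7a11, Nupr1, Cth and Aldh18a1, which makes the proline precursor, led the list, with differences of 3.87, 1.28, 3.71 and 0.82. Atf4 itself differed by 0.17 ± 0.13 (SE) and Ddit3, which encodes the stress factor CHOP, by 0.18 ± 0.15, and neither passed when adjusted over the list alone. Leaving out 1 array gave 0.026 to 0.32 for Atf4 and -0.031 to 0.39 for Ddit3. The hormone gene Fgf21 read 5.41 on every array. Mean levels of the neutrophil list were 7.50 and 6.70 in the WT arrays and 7.87, 8.31 and 6.85 in the Polg mutant arrays, so marrow granulocyte transcripts were not equal between the arrays compared.

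**Figure D2:**
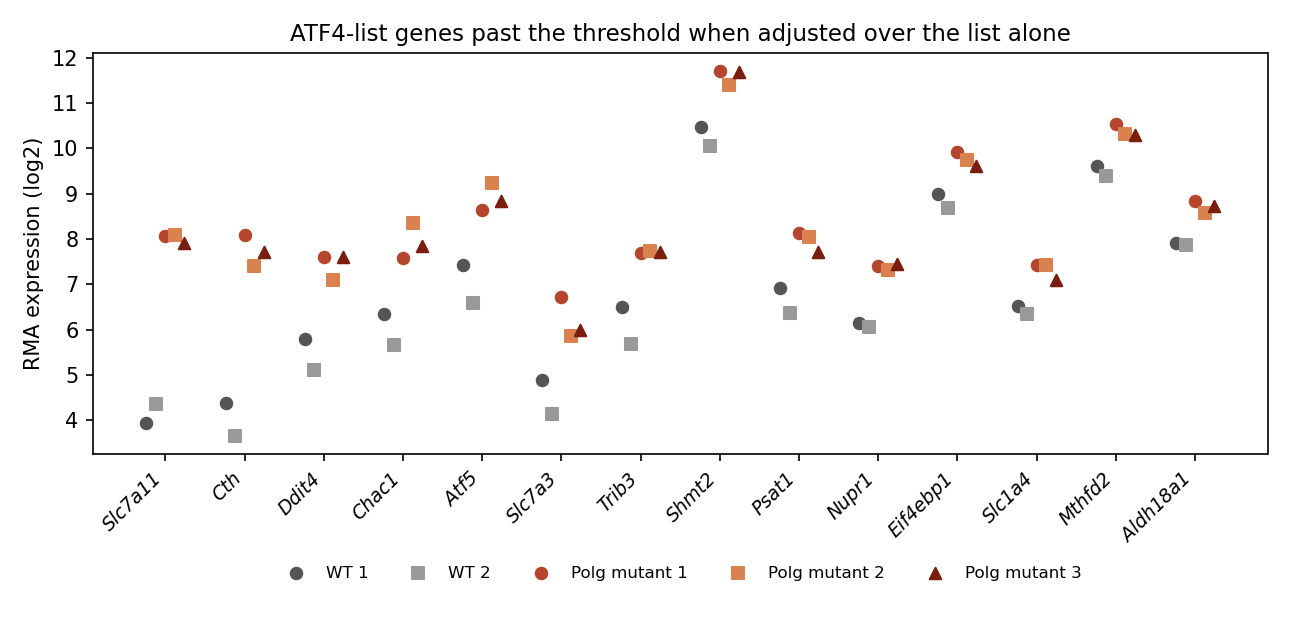
RMA expression on the log2 scale for the 14 ATF4-list genes that passed when adjusted over the list alone, with 1 point per array for the 2 WT and 3 Polg mutant arrays. Slc7a11 stands at 4.16 on average in WT and 8.03 in the Polg mutant, and Cth at 4.02 and 7.73.

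Protein synthesis genes rose as groups. The cytosolic ribosomal protein list was higher by a median of 0.55 over 64 genes (camera adjusted p = 3.81e-27, and adjusted p = 0.231 with an estimated correlation). In 47 of them every Polg mutant array lay above both WT arrays and in 0 below both. With limma, 41 members had an unadjusted p under 0.05, 38 were higher past the threshold when adjusted over the list alone and 0 over all genes tested. Rpl13 rose by 1.14, Rpl29 by 0.67, Rplp1 by 0.85 and Rps12 by 1.33 within the list. Ribosomal protein genes have many processed pseudogenes, and probes may not separate them from the parent genes. Ribosome biogenesis genes rose by a median of 0.35 over 29 genes (camera adjusted p = 1.01e-11, and adjusted p = 0.311 with an estimated correlation). Adjusted over the list alone, limma passed 9 as higher and 1 as lower, and 0 over all genes tested, with 16 at an unadjusted p under 0.05. Polr1a, the largest subunit of RNA polymerase I, was higher by 0.63 and Nop58 by 0.67, while Ubtf, which recruits that polymerase to ribosomal DNA, was lower at -0.54. Small nucleolar RNAs, which guide ribosomal RNA modification, had been fixed as a check of the samples, and this check moved. They rose by a median of 0.35 over 78 transcripts (camera adjusted p = 1.01e-11, and adjusted p = 0.231 with an estimated correlation). With limma 12 passed when adjusted over the list alone and 0 over all genes tested, with 29 at an unadjusted p under 0.05, and Snord49b and Snora44 were each higher by 1.18. Many of these RNAs lie in introns of ribosomal genes. Whether RNA recovery or quality differed between the samples was not tested.

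Cell cycle genes fell as groups. The G2/M and mitosis list fell by a median of 0.40 over 36 genes (camera adjusted p = 5.37e-22, and adjusted p = 0.311 with an estimated correlation). In 33 of these every Polg mutant array lay below both WT arrays and in 0 above both. With limma, 30 members had an unadjusted p under 0.05, 29 were lower past the threshold when adjusted over the list alone and 0 over all genes tested. Ttk differed by -0.65, the spindle assembly factor gene Tpx2 by -0.60, and the mitotic kinesin genes Kif20a and Kif4 by -0.58 and -0.46. DNA replication and S phase genes fell by a median of 0.31 over 35 genes (camera adjusted p = 1.01e-11, and adjusted p = 0.417 with an estimated correlation). None of these passed with limma when adjusted over the list alone or over all genes tested, although 27 were lower on every Polg mutant array and 15 had an unadjusted p under 0.05. The flap endonuclease gene Fen1 differed by -0.47 and Uhrf1, which maintains DNA methylation, by -0.60. Replication-dependent histone genes fell by a median of 0.25 over 21 genes (camera adjusted p = 5.12e-05, and adjusted p = 0.231 with an estimated correlation), with H2bc21 at -0.43 as the 1 gene past the threshold when adjusted over the list alone, 3 at an unadjusted p under 0.05 and 0 past the threshold over all genes tested. Cdkn1a was higher by 2.99 ± 0.38 (SE), from 6.98 ± 0.49 (SD, n = 2) to 9.97 ± 0.46 (SD, n = 3), with a limma adjusted p of 0.224 over all genes and of 0.0368 when adjusted over the p53 target list alone. The p53 list as a whole, 19 genes, did not pass camera (adjusted p = 0.126). In it Zmat3 differed by 0.64, from a WT level of 5.08 not shown to be above background, and the translesion polymerase gene Polk by -0.59.

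**Figure D3:**
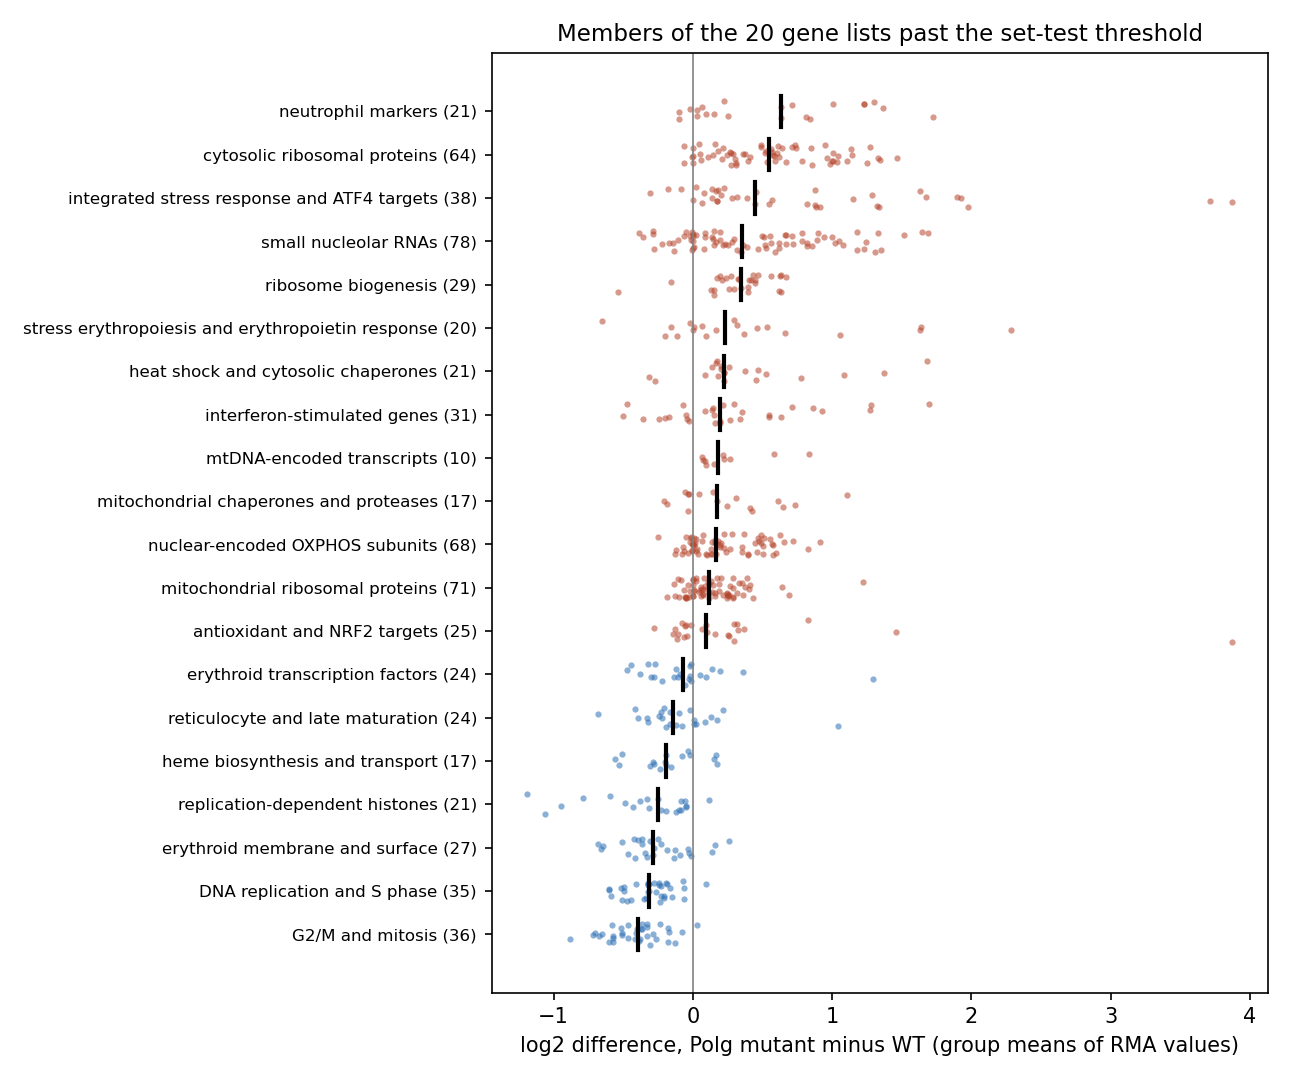
Log2 difference, Polg mutant minus WT, of each measured member (points) of the 20 gene lists past the camera threshold at the preset correlation, with the list median as a black bar, the number of members in parentheses, and red for lists that rose and blue for lists that fell. The ribosomal protein list has its median at 0.55 and the G2/M list at -0.40.

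Genes of red cell structure and of heme synthesis and transport were lower as groups. The neutrophil list means of these arrays were 7.50 and 6.70 in WT and 7.87, 8.31 and 6.85 in the Polg mutant. Whether a different share of other cells lowered the genes of red cell structure and heme synthesis was not tested. The erythroid membrane and surface list fell by a median of 0.29 over 27 genes (camera adjusted p = 2.25e-10, and adjusted p = 0.311 with an estimated correlation). In 20 genes every Polg mutant array lay below both WT arrays and in 1 above both. With limma, 17 had an unadjusted p under 0.05, 15 were lower past the threshold when adjusted over the list alone and 0 over all genes tested. The water channel gene Aqp1 differed by -0.64, and Tmod1 and Add1, which cap actin filaments in the membrane skeleton, by -0.66 and -0.42. Slc4a1, the band 3 anion exchanger, differed by -0.13 ± 0.05 (SE) from a WT level of 13.52 ± 0.09 (SD, n = 2), near the top of the scale, and by -0.067 without WT replicate 1. Heme biosynthesis and transport genes fell by a median of 0.20 over 17 genes (camera adjusted p = 0.000175, and adjusted p = 0.231 with an estimated correlation). Without WT replicate 1 their median was -0.10 and camera no longer called them (adjusted p = 0.0885). With limma 3 passed as lower when adjusted over the list alone and 0 over all genes tested, with 6 at an unadjusted p under 0.05. Slc25a38, which imports glycine for heme synthesis, differed by -0.56, Slc25a37, the mitochondrial iron importer, by -0.20, and Fech, the enzyme that inserts the iron, by -0.08. Reticulocyte and late maturation genes had a median of -0.14 over 24 genes (camera adjusted p = 0.0125, and adjusted p = 0.322 with an estimated correlation), with a median of -0.079 and adjusted p = 0.447 without WT replicate 2, and an adjusted p of 0.115 without Polg mutant replicate 3. Fbxo7 differed by -0.25 and Nprl3 by -0.42, both past the threshold with limma when adjusted over the list alone, with 0 over all genes tested. Erythroid transcription factor genes had a median of -0.07 over 24 genes (camera adjusted p = 0.0188, and adjusted p = 0.493 with an estimated correlation), and the median was -0.18 without WT replicate 2 (adjusted p = 0.00139). Camera did not call them without WT replicate 1 (median -0.034, adjusted p = 0.842) or without Polg mutant replicate 3 (adjusted p = 0.0599). With limma 0 passed when adjusted over the list alone, and Lmo2 differed by -0.28, Bcl11a by 0.36, Gata1 by -0.12 ± 0.05 (SE) and Klf1 by -0.13 ± 0.06, or by -0.049 and -0.080 without WT replicate 1.

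Genes of the response to erythropoietin, the hormone that drives red cell production after blood loss, rose by a median of 0.23 over 20 genes (camera adjusted p = 5.12e-05, and adjusted p = 0.322 with an estimated correlation). Without WT replicate 2 the median was 0.14. With limma, 6 passed as higher and 1 as lower when adjusted over the list alone and 0 over all genes tested, with 10 at an unadjusted p under 0.05. Erfe was higher by 2.28 ± 0.21 (SE), the JAK-STAT feedback inhibitor genes Cish and Socs3 by 1.64 and 0.66, and the cytokine gene Osm by 1.06. The WT level of Socs3, 5.22, was not shown to be above background. Epor, the erythropoietin receptor gene, was lower at -0.65 ± 0.14 (SE). The early erythroid progenitor list did not pass camera (16 genes, adjusted p = 0.347), although its member Podxl, a sialomucin gene, was 12.7-fold higher, from a WT level of 4.97 not shown to be above background, and passed with limma when adjusted over that list alone, and Myc was higher by 0.91. The iron list did not pass either (29 genes, camera adjusted p = 0.795), with Tfrc, the transferrin receptor gene, at -0.39 ± 0.16 (SE), or -0.17 without WT replicate 1 and -0.61 without WT replicate 2, the ferrireductase gene Steap3 at -0.70 and Exoc6, which acts in transferrin recycling, at 0.31.

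Of the mitochondrial lists, 4 rose by small medians and others did not pass camera. Polg read 6.97 on every array, a single value that does not check the labels, since the mutant allele carries a point mutation and keeps its transcript. Transcripts encoded by mitochondrial DNA rose by a median of 0.18 over 10 genes (camera adjusted p = 5.48e-05, and adjusted p = 0.470 with an estimated correlation). Without WT replicate 2 this median was 0.10 and camera no longer called the list (adjusted p = 0.0785). The complex I subunit gene ND3 was higher by 0.83 ± 0.09 (SE) and was the 1 member past the limma threshold when adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 0 over all genes tested. ND4 and COX3 differed by 0.10 and 0.26. Nuclear-encoded subunits of oxidative phosphorylation rose by a median of 0.17 over 68 genes (camera adjusted p = 1.18e-08, and adjusted p = 0.342 with an estimated correlation), with 27 higher and 1 lower on every Polg mutant array. With limma 0 passed when adjusted over the list alone or over all genes, with 19 at an unadjusted p under 0.05, and Ndufa7, Ndufs8 and Atp5e were higher by 0.58, 0.60 and 0.91. Mitochondrial ribosomal protein genes rose by a median of 0.12 over 71 genes (camera adjusted p = 4.85e-06, and adjusted p = 0.231 with an estimated correlation). Their median was 0.07 without WT replicate 1 and 0.06 without WT replicate 2, and Mrpl15 and Mrpl38 were higher by 0.32 and 0.39. With limma 0 members passed when adjusted over the list alone or over all genes, with 11 at an unadjusted p under 0.05. Mitochondrial chaperone and protease genes rose by a median of 0.17 over 17 genes (camera adjusted p = 0.000729, and adjusted p = 0.322 with an estimated correlation), but camera did not call them without WT replicate 2 (adjusted p = 0.0773), and the median was 0.10 without WT replicate 1. With limma 6 passed when adjusted over the list alone and 0 over all genes tested, with 7 at an unadjusted p under 0.05, among them Hspd1, Hspa9, the protease gene Clpp at 0.24 and the prohibitin gene Phb2 at 0.15. The lists of the tricarboxylic acid cycle (24 genes, median -0.015, adjusted p = 0.568) and fatty acid oxidation (19 genes, median -0.0086, adjusted p = 0.795) did not pass camera. Nor did mitochondrial DNA maintenance and biogenesis (25 genes, adjusted p = 0.811), with Dguok at -0.35 and Polg2, the accessory subunit gene of the polymerase, at -0.31, and the DNA ligase gene Lig3 at 0.43, or 0.26 without WT replicate 1.

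Autophagy genes did not shift in a common direction as a group. The core autophagy list had a median of -0.00315 over 41 genes (camera adjusted p = 0.691), the mitophagy list -0.01 over 21 genes (adjusted p = 0.795), the lysosome list 0.10 over 37 genes (adjusted p = 0.258) and the mTORC1 pathway list -0.02 over 39 genes (adjusted p = 0.918). Fry's mixed test gave an unadjusted p of 0.104 for core autophagy, 0.000126 for mitophagy, 0.0089 for lysosome and 4.63e-05 for mTORC1. Groups did not overlap for 5 higher and 4 lower mitophagy genes, where chance gives 20% of untied genes in either direction together. Members of the mitophagy, lysosome and mTORC1 lists may thus differ in both directions. The selective autophagy receptor gene Sqstm1 was higher by 0.44 ± 0.10 (SE), on every Polg mutant array, with a limma adjusted p of 0.319. Atg7, the floxed gene in these crosses, read 7.71 in WT replicate 2 and 7.74 in each of the other arrays. The equal values are exact ties of the kind described above, so they do not tell whether Atg7 was intact in any sample. Map1lc3b differed by 0.15 ± 0.13 (SE), Ulk1 by 0.03 ± 0.06, Bnip3 by -0.04 ± 0.06 and Pink1 by 0.30 ± 0.11. Bnip3 read 4.15 to 4.30 on all arrays, a level not shown to be above background, and Bnip3l was not analysed here. Without WT replicate 2 Map1lc3b, Ulk1 and Bnip3 changed sign, at -0.0097, -0.015 and 0.0022, and Ulk1 also did when arrays were centred on the brighter genes. Wipi1 and Atg4d were lower at -0.22 and -0.68, the fission genes Dnm1l and Fis1 differed by -0.26 and 0.34 (-0.16 and 0.17 without WT replicate 1), and the lysosomal protease genes Ctsb and Ctsl by -0.38 and 0.72 (0.44 for Ctsl without WT replicate 1). Within the mTORC1 list, limma passed 2 as higher and 2 as lower when adjusted over the list alone and 0 over all genes tested, with 11 at an unadjusted p under 0.05. The lower ones were Rragd, a Rag GTPase gene, at -1.43 and Nprl3 at -0.42, and the higher ones were the translation repressor genes Eif4ebp1 at 0.91 and Eif4ebp2 at 0.38.

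Cytosolic heat shock and chaperone genes rose by a median of 0.22 over 21 genes (camera adjusted p = 3.18e-06, and adjusted p = 0.360 with an estimated correlation). None passed with limma when adjusted over the list alone or over all genes tested, with 8 at an unadjusted p under 0.05. Bag3 was higher by 1.08 and Hspa1a by 1.37, the latter from a WT level of 5.11 not shown to be above background. Antioxidant genes of the NRF2 pathway had a median of 0.09 over 25 genes (camera adjusted p = 0.0442, and adjusted p = 0.470 with an estimated correlation). Camera did not call that list without either WT array (adjusted p = 0.292 and 0.191) or without Polg mutant replicate 1 or 2 (adjusted p = 0.0949 and 0.0904), and without Polg mutant replicate 1 the median was 0.036. With limma 3 passed as higher when adjusted over the list alone and 0 over all genes tested. Slc7a11 belongs to it too, and the glutathione synthetase gene Gss was higher by 0.83. Interferon-stimulated genes had a median of 0.20 over 31 genes (camera adjusted p = 0.0187, and adjusted p = 0.470 with an estimated correlation), with Oas2 higher by 1.27, Cmpk2 at -0.50, 9 genes at an unadjusted p under 0.05 and 0 past the limma threshold over the list alone. Camera did not call them without WT replicate 1 (median 0.10, adjusted p = 0.335) or without Polg mutant replicate 1 or 3 (adjusted p = 0.0521 and 0.0599).

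Markers of other marrow cells and of sex were read in the same arrays. Neutrophil marker genes were higher by a median of 0.63 over 21 genes (camera adjusted p = 0.0231, and adjusted p = 0.813 with an estimated correlation). In limma 1 of these genes had an unadjusted p under 0.05, the chitinase-like gene Chil3. It was higher by 1.73, from a WT level of 4.63 not shown to be above background. Camera did not call the neutrophil list without WT replicate 2 (median 0.12), without Polg mutant replicate 1 (adjusted p = 0.165) or without Polg mutant replicate 2 (median 0.23, adjusted p = 0.412). Lists for monocytes and macrophages, B cells, plasma cells, T and NK cells, megakaryocytes, mast cells and eosinophils, stroma and endothelium, and stem cells did not pass (camera adjusted p from 0.0721 to 0.795), although the platelet glycoprotein gene Gp9 was lower at -1.36 and passed with limma when adjusted over its list alone, while Plek of the same list was higher by 1.45. Xist, transcribed from the inactive X chromosome of female cells, read 5.76 in WT replicate 1 and 11.9 to 12.1 in the other arrays. The Y-linked genes Uty, Eif2s3y and Kdm5d read 7.39, 7.16 and 6.33 in WT replicate 1 and between 2.87 and 3.50 in the other arrays. The sex pattern of WT replicate 1 therefore differed from that of the other arrays, and without it the medians of the ATF4, ribosomal protein and G2/M lists were 0.56, 0.55 and -0.35.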

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

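Leaving out each array was set beforehand, but its use as tests of the male-like WT array, and the test of the neutrophil trend within groups, were chosen only after the result was seen, while the others in this part were set before it. Probe sets without a gene symbol were not used in the comparison. Among these 16010, 27 were higher by a mean of at least 2 log2 units with every Polg mutant array above both WT arrays, and 6 were lower by as much. They were singled out as a signal in data that no comparison used. The probe sets with IDs 17285521 and 17285523 were higher by 4.51 and 4.31, from WT means of 2.31 and 4.903 not shown to be above background, so these differences are not exact. The probe set with ID 17209723 was lower, at -2.45, with a Polg mutant mean of 5.03 under the same limit. Among named genes the counts by the same measure were 20 higher and 5 lower.

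Exactly equal values on different arrays occurred in 56.6% of probe sets. A floor set for dim probe sets would put the tie at the 2 lowest values, yet of 9114 probe sets with a single tied pair 0.955% had it there. Median polish of 5 arrays, the summary step usual in RMA, would put it at the middle-ranked value, and 98.5% had it there. The ties may thus come from median polish, which does not use the genotype labels, and no biological explanation was tested. In the simulation changed genes were less often tied, so which genes are tied may still depend on differences between the groups.

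The ATF4 list had a median difference of 0.45. Without the WT array that had the Y-linked transcripts the median was 0.56 (95% bootstrap interval over genes 0.32 to 0.98), which argues against that array as the whole cause. That comparison rests on 1 WT array, and its interval holds no spread between arrays. With the neutrophil list mean as a covariate the median was 0.44, with a wide interval of 0.14 to 0.83. Its lower bound was too low for the rule set beforehand, so the covariate test did not decide. The trend of ATF4-list genes with the neutrophil mean within groups would give a median of 0.059 (interval over genes 0.023 to 0.11). Across the Polg mutant arrays the neutrophil mean read 7.87, 8.31 and 6.85 and the ATF4-list mean 8.51, 8.49 and 8.46. The within-group trend and the Polg mutant values argue against granulocyte content as the cause of most of the shift. That trend was tested only after the result was seen, and its interval resamples genes, not arrays. A smaller part stays open, since the WT array with more neutrophil transcripts (7.50 against 6.70) also had the higher ATF4-list mean (7.84 against 7.55), and 5 arrays give little precision to a trend. CD45 depletion would remove granulocytes, and 18 of the 21 neutrophil genes, of which 0 belong to another list, still read above a log2 of 6 on at least 2 arrays, with its brightest member Elane at 10.6 to 11.8 and Mpo at 10.5 to 11.6, genes picked after their values were seen. An effect of the Polg genotype on ATF4 targets may hold as a hypothesis, with inheritance of the Cre allele and the response to bleeding untested.

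The ribosomal protein list was higher by 0.55 and the G2/M list lower at -0.40. After a trend with genomic span was removed the medians were 0.55 and -0.39, and after a trend with brightness 0.60 and -0.29, with bootstrap intervals of 0.37 to 0.61 and -0.49 to -0.33 for span, and 0.46 to 0.76 and -0.41 to -0.25 for brightness. Without the male-like WT array they were 0.55 and -0.35. The values after removal of the brightness trend and without that array argue against brightness and that array as the whole cause. The test of span cannot decide, because across all genes, most of them tied, the difference hardly followed span (Spearman's rho -0.064). Little was therefore removed, and span in the genome is not transcript length. The bootstrap intervals resample genes, not arrays. A shift in the stages of the erythroid cells selected, as well as an effect of genotype within each stage, may account for both lists, and neither was tested apart.

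The 10 splits of the 5 arrays into 2 and 3 are too few for a share under 0.05. The real split gave 2110 genes at an unadjusted p under 0.05 and the highest other split 1707, for WT replicate 2 with Polg mutant replicate 3, so that 1 split, the real one, gave as many. It gave 20 lists past the camera threshold and the highest other split 20, for Polg mutant replicates 1 and 2, so that 2 splits, with the real one counted, gave as many. That other split also kept both WT arrays together, while splits pairing a WT with a Polg mutant array gave 3 to 8 lists. Among untied genes above a log2 of 6 the real split gave 487 genes past the limma threshold and the highest other split 0, so that 1 split, the real one, gave as many.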

How the results depend on the processing

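The fits to untied genes and the prior variance from untied genes were chosen after seeing the data, and the other alternatives before. Where limma over all genes called 0 higher and 0 lower, untied genes gave 73 and 41, and untied genes above a log2 of 6 gave 247 and 240. The untied prior gave 5 and 0. The cause was shown in part by construction, since fewer genes were tested and the prior variance was larger and steadier. In the fits to untied genes the filter itself also favoured genes that differ between arrays. Genes above a log2 of 6 gave 6 and 5, renewed quantile normalization 8 and 1, centring on the brighter part 30 and 18, no moderation 4 and 1, and an adjusted p under 0.1 gave 2 and 3; for these the cause was not tested. A log2 difference of at least 1, a trend, a robust trend, array weights, median centring, genes above the median brightness, the mean over probe sets and all probe sets gave 0 and 0. The count of genes at unadjusted p under 0.05 was 3599 over all probe sets, against 2110, since more features were tested. The count of lists was 0 with an estimated correlation and 7 with fry, against 20, and between 15 and 25 under the other settings. Leaving out 1 array gave 0 to 713 higher and 0 to 1068 lower genes, with both upper ends without WT replicate 1, 1623 to 4475 genes at an unadjusted p under 0.05 and 16 to 21 lists.

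Of the list results under these settings, 334 kept direction and call and 66 lost the call, 20 of them with an estimated correlation and 13 with fry, and 0 reversed. Outside these and the left-out arrays, the lists that lost it were erythroid transcription factors, reticulocyte maturation, NRF2 targets, neutrophil markers, interferon-stimulated genes and histones. Lists were not run with a robust trend, no moderation or the untied prior. Of the values for 119 named genes, 2116 kept direction and call, 215 passed where they had not, and 13 changed sign. With 1 array left out the values ran from -0.19 to 6.19 for Xist, -3.02 to 0.21 for Kdm5d, -0.0097 to 0.32 for Map1lc3b, -0.031 to 0.39 for Ddit3, -0.015 to 0.081 for Ulk1, -0.082 to 0.0022 for Bnip3, -0.28 to 0.78 for Elane, -0.43 to 0.62 for Mpo and -1.16 to 2.996 for Kcnma1. With centring on the brighter part the log2 difference of Atg7 was -0.031 and the log2 difference of Ulk1 -0.012, and with renewed quantile normalization that of Atg7 was -0.000965. The reversals of Xist and Kdm5d follow from leaving out the 1 array with Y-linked transcripts; for the other genes the cause was not tested. No signal over background was known, so its limit for dim genes was not measured.

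With the replicate number as a block, limma called 0 higher and 0 lower genes, the count of genes at unadjusted p under 0.05 was 2146 and camera called 20 lists. The lists of erythroid transcription factors (adjusted p = 0.184), reticulocyte maturation (0.101) and interferon-stimulated genes (0.108) were not called with the block. Deviations from the group means correlated across genes at 0.19 for both arrays numbered 1 and at -0.20 for both numbered 2, below the 0.31 for WT replicate 2 with Polg mutant replicate 3. With 2 WT arrays the WT deviations mirror each other, which fixes the signs in pairs. These correlations therefore cannot show whether arrays of the same number share more than that number.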

Other observations

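The tests of gene neighbourhoods in this part were chosen only after the result was seen. Some further lists did not pass camera. Hypoxia targets, 18 genes, came nearest (adjusted p = 0.0506), followed by cholesterol synthesis (adjusted p = 0.0596) and inflammatory cytokines (adjusted p = 0.108). The proteasome (adjusted p = 0.779), sex-linked transcripts (0.790) and glycolysis (0.918) showed no shift past the threshold. Of the globin list 3 embryonic members were measured, too few for the test.

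Several genes outside the lists, chosen after their values were seen, differed by large amounts on every Polg mutant array. Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, was 12.9-fold lower, with 7.94 ± 0.60 (SD, n = 2) in WT and 4.25 ± 0.36 (SD, n = 3) in the Polg mutant, a level not shown to be above background. The transcriptional corepressor gene Runx1t1 differed by -2.27 ± 0.28 (SE), the T-type calcium channel gene Cacna1g by -2.13 ± 0.29 and the glutathione transferase gene Gstt1 by -1.52 ± 0.16. Calcrl, a receptor gene for adrenomedullin, was 5.01-fold higher and the adaptor gene Grb10 4.45-fold higher, from a WT level of 5.58 not shown to be above background. The log2 difference of Calcrl, 2.33, was 1.57 without WT replicate 1 and 3.09 without WT replicate 2. None passed limma over all genes (adjusted p from 0.200 to 0.325), and all passed among untied genes above a log2 of 6 (limma adjusted p from 0.00952 to 0.033). Kcnma1, a potassium channel gene, read 12.8 on Polg mutant replicate 2 and 4.51 to 7.77 on the other arrays.

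Tmem67, Rbm12b2 and Cibar1, which lie within 10 measured genes of each other in the GRCm38.p6 gene table, were higher by 3.68, 2.54 and 1.02. It was asked whether a local cluster of changed genes is a candidate explanation. Of 10000 shuffled gene orders, 15.3% held at least 1 such window of 10 genes with 3 members higher by at least 1 log2 unit, so 1 such neighbourhood is not rare by chance. The data held 2, the other with Hspa9, Mir1949 and Snora74a, and 1.70% of shuffled orders held as many. Whether changed genes lie together more than by chance therefore stays open, in a test framed after the first window was seen. Runx1t1, in the same neighbourhood, was lower.

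Flanking DNA carried along with the mutant Polg allele was also considered as a candidate source of differences. Among the 200 measured genes nearest to Polg by that order, 5.50% had an unadjusted p under 0.05, against 9.60% of other genes, a ratio of 0.573 (odds ratio interval 0.27 to 1.01, Fisher's exact test, two-sided, p = 0.0523). An excess near Polg was thus not seen. Because 200 genes could make up only a small part of the 2110 at that unadjusted p, the test bears only on a local excess. The count does not address single large differences or DNA carried along elsewhere in the genome.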
